A study of Mus musculus with 10 samples.

How the data were processed

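Polyadenylated RNA of 10 primary pancreatic tumours of KPF mice was sequenced on an Illumina NovaSeq instrument after library preparation with a KAPA mRNA HyperPrep kit, per the labels' protocols. Mice of 6 to 12 weeks of age were used, per the labels. Each tumour was assigned to its group from its title, which gives the Grem1 genotype and a replicate number, and the groups have 5 libraries each. The description of the samples calls them bulk tumour tissue and the extraction protocol mentions sorted cells. The labels do not settle which holds for these libraries. The labels name no batch, sex or date. Each title also carries a tumour ID with a number from 25 to 40 whose meaning the labels do not give.

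The authors deposited a table of estimated counts per gene for all 10 libraries. Per the submitters' processing notes the tools were bcl2fastq 2.0, FastQC 0.11.9, HISAT2 2.2.1, RSEM 1.3.3 and DESeq2 1.32.0, and the build was mm10. The annotation release and whether the counting used strand are not given in the sources used here. The deposited estimated counts need not be whole: 7.96% of the values in the table were not. An estimated count shares reads that fit several genes between them, so values of near-identical genes such as Hspa1a and Hspa1b are uncertain. Genes whose exons overlap an exon of another gene, such as Greb1, Tiparp and Tff1, could hold reads of the other gene. The authors also deposited 1 file per tumour with normalized values on a log2 scale for 25407 genes, from -1.29 to 17.5, and the kind of transformation is not named. Those files were used for 1 alternative alone. The genes they lack had a summed count of at most 5.47 over the 10 libraries.

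Estimated counts were rounded to whole numbers. Genes with enough counts were chosen with filterByExpr of edgeR 4.0.16 (minimum count 10), which kept 16565 of 55487 genes. Libraries were scaled by the trimmed mean of M values, and groups were compared with edgeR's quasi-likelihood F test with robust dispersions and Benjamini-Hochberg adjustment at 0.05. Standard errors (SE) of log2 fold changes were taken from the F statistic. A positive log2 fold change means a higher value in libraries labelled deleted. CPM values use the scaled library sizes, and log2 CPM has a prior count of 2. Total estimated counts ran from 10159891 to 18571519, and the common biological coefficient of variation was 0.355, so spread between tumours rather than counting limited the precision of all but the rarest genes. No 2 libraries of a group agreed within sampling noise: the lowest chi-square per degree of freedom within a group was 25.6. The closest libraries were of different groups, wild-type tumour 2 and labelled-deleted tumour 4, at 13.3. R was version 4.3.3, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.

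Before the data were examined, 36 gene lists were fixed, covering programmes (BMP, epithelial, mesenchymal, tumour subtype, signalling and stress) and cell types. Lists with at least 3 tested members were tested with camera of limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. The same test with an estimated correlation, fry, and exact two-sided permutation of list scores over all 252 assignments stood beside it. The smallest p that this permutation can give is 0.00794. A list score is the mean log2 CPM of the tested members minus the wild-type mean of each gene. The skeletal muscle list had 0 tested members and the intestinal epithelium list had 2, so neither was tested, and the sex-linked list served only to describe the libraries. The rule for the genes named in the text was also fixed in advance: a panel of 9 genes, the 10 largest changes in each direction among genes past the threshold (there were none), and up to 4 members with the smallest p in each list described. Genes outside this rule are said to have been chosen after their values were seen. Of 55487 gene identifiers, 55141 are in GENCODE M21, whose GRCm38 coordinates are given.

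Alternatives were DESeq2, limma-voom with and without sample quality weights, other scalings, other low-count filters, non-robust dispersions, a threshold of 0.1, a test against a fold of 1.5, blocks by replicate number and by tumour ID number, covariates for acinar content and for Ddx3y, leaving out each library in turn, and the deposited log2 values with limma. A covariate for B-cell content, an estimated correlation with labelled-deleted tumour 1 left out, and a fit without labelled-deleted tumours 1 and 2 were added after the data were seen.

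The pipeline was tested on simulated data drawn from the gene means, library sizes and dispersions of this comparison of 5 against 5, with 200 changed genes. Over 16467 genes in the simulated fit, edgeR recovered 10% of genes changed 1.5-fold, 46% of those changed 2-fold, 74% of those changed 4-fold and 92% of those changed 8-fold. Of its calls 2.63% were genes that had not been changed. DESeq2 recovered 32%, 66%, 90% and 92% at the same folds, and 23.5% of its calls had not been changed. With nothing changed edgeR called 0 genes and DESeq2 called 18. With the epithelial identity list raised 1.5-fold and genes drawn independently, camera gave that list an adjusted p of 3.69e-11 with the preset correlation and 0.00149 with an estimated one, and called 0 of the other lists.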

Results

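Gene expression was measured by polyA RNA sequencing of primary pancreatic tumours from KPF mice, a mouse model of pancreatic cancer kept on the C57BL/6J background. Grem1 encodes Gremlin 1, a secreted antagonist of bone morphogenetic proteins (BMPs). The series holds 5 tumours labelled Grem1 wild-type and 5 tumours labelled Grem1-deleted, described as biological replicates. Mice of the deleted group received tamoxifen at 100 mg/kg once a day for 5 days from 5 weeks of age, and mice of the wild-type group received peanut oil on the same schedule. Genotype and tamoxifen were therefore given to the same animals and cannot be separated by any comparison of these libraries. The labels describe the material as bulk tumour tissue, while their extraction protocol speaks of sorted cells. Markers of acinar, immune, endothelial and fibroblast cells were all measured. Every library held epithelial Epcam (172 to 605 CPM), fibroblast Col1a1 (1815 to 10434 CPM) and macrophage Lyz2 (383 to 2834 CPM). These values argue against a sort for 1 cell type, and other kinds of sorting are not covered by them. Col1a1 and Lyz2 were chosen after their values were seen. Total estimated counts ranged from 10159891 to 18571519 per library. Mitochondrial genes took between 1.37% and 2.44% of the counts. Of 55487 genes in the table, 16565 had enough counts to be tested.

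The targeted gene was examined first. Grem1 (ENSMUSG00000074934) lies on the minus strand of chromosome 2 from 113746164 to 113758646 in GRCm38, the assembly also called mm10. It has 2 annotated exons, and its coding sequence, from 113749603 to 113750154, lies in exon 2. Grem1 was not lower in the libraries labelled deleted. The wild-type tumours held 15.7, 43.1, 23.0, 3.97 and 9.48 CPM (counts scaled to a common library size), with a mean of 19.1 ± 15.2 CPM (SD, n = 5). The tumours labelled deleted held 47.6, 110.1, 12.6, 6.83 and 23.7 CPM, with a mean of 40.2 ± 42.1 CPM (SD, n = 5). The log2 fold change of deleted over wild-type was 1.08 (SE 0.79), which was within the spread between tumours (edgeR quasi-likelihood test, adjusted p = 0.761). An exact two-sided permutation test of log2 CPM gave p = 0.381. Leaving out labelled-deleted tumour 2, the highest of all, gave a log2 fold change of 0.25, and leaving out wild-type tumour 2, the highest of its group, gave 1.60. Leaving out labelled-deleted tumours 1 and 2 together, which both stood apart as described below, turned it to -0.40 (SE 0.71). Those tumours held the most Grem1 of their group, so leaving them out had to lower the log2 fold change. Counts per gene do not show which part of a gene the reads came from, and the deleted part is not stated in the labels. The measurement therefore does not show the deletion, and the groups are named below by their labels alone.

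**Figure D1:**
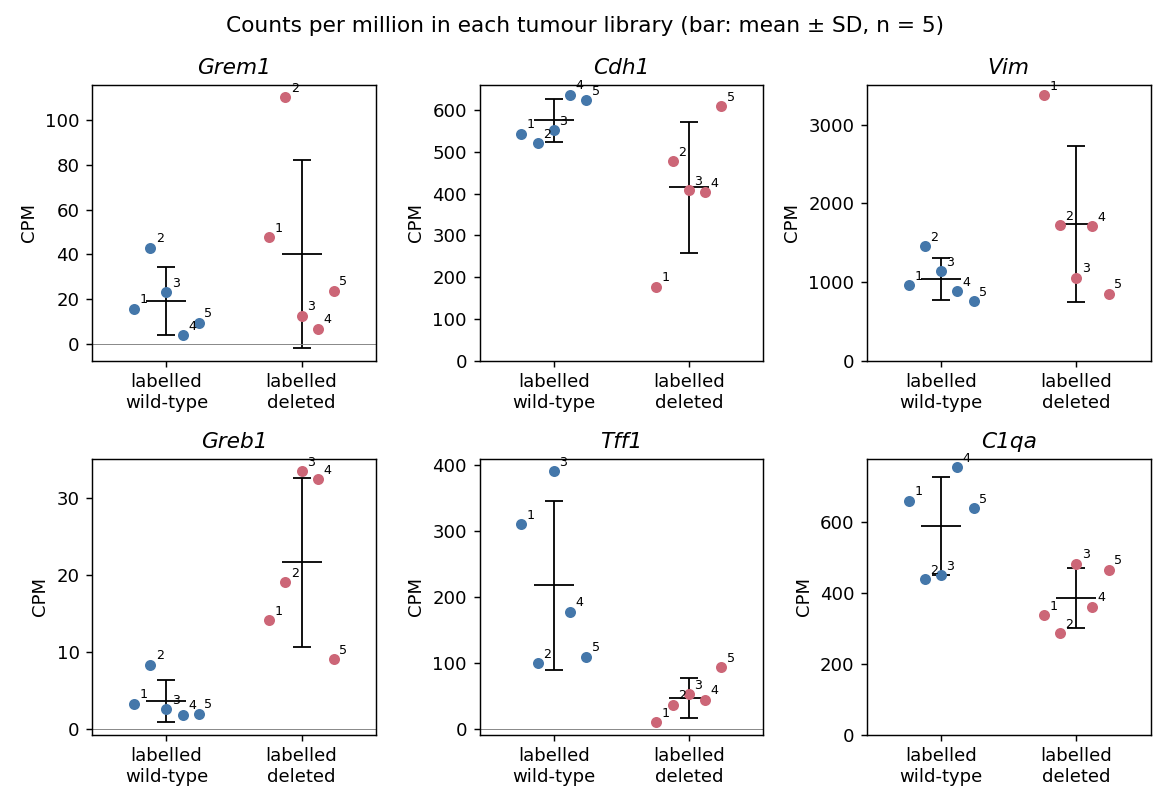
CPM (vertical axes, each with its own range) of 6 genes in each tumour library, numbered by replicate, for the libraries labelled wild-type (blue) and deleted (red); black bars give the mean ± SD of 5 libraries. Grem1 overlapped between the groups, all 5 libraries labelled deleted lay above the 5 wild-type libraries for Greb1, and all 5 lay below them for Tff1.

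The comparison asked how the transcriptome of tumours labelled Grem1-deleted differed from that of wild-type tumours. At the level of single genes, 0 of 16565 genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, and the lowest adjusted p was 0.759. At an unadjusted p under 0.05 there were 983 genes, of which 575 were higher and 408 were lower in the libraries labelled deleted. Chance alone would give 828. DESeq2, fitted to 31198 genes, called 7 genes and limma-voom called 0. The DESeq2 calls were chosen after their values were seen. They were Greb1, with a log2 fold change of 2.58 (SE 0.48), and Gpnmb, a transmembrane glycoprotein of macrophages and tumour cells, with 1.84 (SE 0.33), both higher in the libraries labelled deleted. The other 5 were lower: Chmp2b at -0.39 (SE 0.08), Ltb4r1, a leukotriene B4 receptor, at -1.29 (SE 0.24), Penk, the enkephalin precursor, at -1.36 (SE 0.27), C1qtnf3 at -2.74 (SE 0.61) and Gm49721 at -5.04 (SE 1.11). In 82 genes all 5 libraries labelled deleted lay above all 5 wild-type libraries, and in 72 genes all 5 lay below. Together these are 0.930% of the genes tested, against 0.794% by chance.

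At the level of gene lists, 33 lists fixed before the data were examined had at least 3 tested members. Camera with its preset correlation of 0.01 called 14 of them at an adjusted p under 0.05, 7 lower and 7 higher in the libraries labelled deleted. With a correlation estimated from the data 0 of the 33 were called, and the lowest adjusted p was 0.444. Fry called 0, with a lowest adjusted p of 0.460. Exact two-sided permutation of the list scores gave 0, with a lowest adjusted p of 0.602, but its smallest p of 0.00794 passes over 33 lists only where several lists reach it together, so that count says little. From the estimated correlation and fry, the differences between lists below are descriptions of these 10 libraries.

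Labelled-deleted tumour 1 stood apart from the other 9 libraries. The first principal component took 39.9% of the variance, and this tumour scored 125.7 on it against -38.0 to 12.3 in the others. It held 177 CPM of Cdh1, the epithelial adhesion protein E-cadherin, against 403 to 637 CPM in the other libraries. Its epithelial identity score was -1.81 relative to the wild-type mean on a log2 scale, its proliferation score was 1.46 and its interferon score was 2.81. Its most abundant transcript was Eef1a1, whereas Clu led in all 5 wild-type libraries and in labelled-deleted tumours 3 and 5. A lead other than Clu was not particular to it, since mt-Co1 led in labelled-deleted tumour 2 and Fn1 in labelled-deleted tumour 4. Without this library 9 of the 14 lists were still called with the preset correlation in the same direction.

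Labelled-deleted tumour 2 held transcripts of intestinal epithelium. The genes named here were picked from the list fixed in advance after their values were seen. The apolipoprotein gene Apoa4 stood at 897 CPM, the disaccharidase gene Sis at 293 CPM, the fatty acid carrier Fabp2 at 238 CPM and the lactase gene Lct at 112 CPM. The other 9 libraries held at most 4.72 CPM of Apoa4, 1.16 CPM of Sis, 1.18 CPM of Fabp2 and 0.80 CPM of Lct. Most genes of that list were expressed in too few libraries to be tested. This library also had the highest Grem1 value. Without tumours 1 and 2 of the libraries labelled deleted, 7 of the 14 lists were still called in the same direction, and 0 genes passed.

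**Figure D2:**
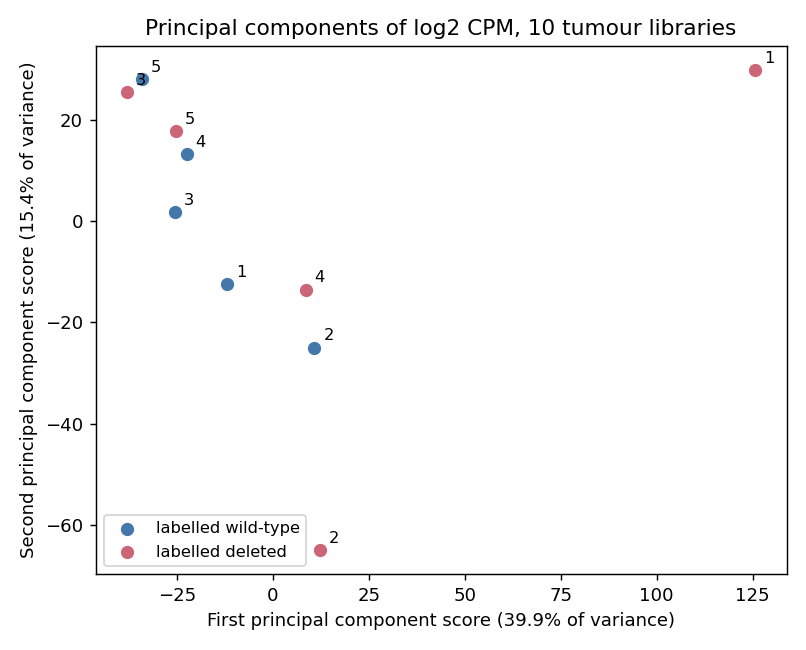
Scores of the 10 libraries on the first and second principal components of log2 CPM, numbered by replicate within each group. Labelled-deleted tumour 1 lies at 125.7 on the first component, which holds 39.9% of the variance, and the other 9 libraries lie between -38.0 and 12.3.

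Of 26 epithelial identity genes, 24 were lower in the libraries labelled deleted, and the median log2 fold change was -0.38 (camera adjusted p = 2.88e-10). With an estimated correlation the adjusted p was 0.568. No member passed the test over all genes, and 0 passed adjusted over the list alone. The members with the smallest p were the keratins Krt7 at -0.66 (SE 0.21) and Krt18 at -0.45 (SE 0.17), the tight junction gene Cldn4 at -0.90 (SE 0.36) and the mucin Muc1 at -0.74 (SE 0.31). Cdh1 was at 575 ± 51.6 CPM in wild-type tumours and 415 ± 157 CPM in those labelled deleted (SD, n = 5), a log2 fold change of -0.47 (SE 0.26). Epcam, another epithelial surface marker, had a log2 fold change of -0.43 (SE 0.26). Without labelled-deleted tumour 1 the list's median was -0.18, Cdh1 was at -0.28 (SE 0.13), and Epcam was at -0.23 (SE 0.12).

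In the list of the classical subtype of pancreatic cancer, 2 members passed adjusted over the list alone, Muc5ac and Tff1, both lower in the libraries labelled deleted. The gastric mucin Muc5ac averaged 256 ± 170 CPM in wild-type tumours and 39.8 ± 24.9 CPM in those labelled deleted, a log2 fold change of -2.68 (SE 0.74). The trefoil peptide Tff1 averaged 218 ± 128 and 47.6 ± 30.3 CPM (SD, n = 5), a log2 fold change of -2.19 (SE 0.56). Both were lower in all 5 libraries labelled deleted than in every wild-type library. Each had an adjusted p of 0.759 over all genes and 0.0443 adjusted over the list alone. Gkn1, a gastric mucosal protein, was at -1.89 (SE 0.83), and at -2.92 (SE 0.74) without labelled-deleted tumour 5. Spink4, in contrast, was at 3.44 (SE 1.56), and 56.3 CPM in labelled-deleted tumour 2 set this value, since the other 9 libraries lay between 0.08 and 2.2 CPM. That tumour is the library with intestinal transcripts. Of 20 members tested, 13 were lower and 7 higher. The median was -0.35 and the mean -0.09 (camera adjusted p = 0.00011), and with an estimated correlation the adjusted p was 0.568. Without labelled-deleted tumour 1 the median was -0.16, and without labelled-deleted tumour 2 it was -0.59. The 9 tested members of the basal-like subtype had a median of 0.20 and were not called (camera adjusted p = 0.842).

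Mesenchymal genes went both ways. Their median log2 fold change was -0.02 over 16 genes, with 7 higher and 9 lower, while their mean was 0.19 (camera adjusted p = 0.831). Vim, the intermediate filament vimentin, averaged 1040 ± 270 CPM in wild-type tumours and 1744 ± 992 CPM in those labelled deleted (SD, n = 5), a log2 fold change of 0.75 (SE 0.35). Labelled-deleted tumour 1 held 3376 CPM of Vim, and without it the log2 fold change was 0.36 (SE 0.25). Wnt5a was at 0.59 (SE 0.23), S100a4 at 1.44 (SE 0.58) and N-cadherin (Cdh2) at 0.81 (SE 0.38). Without labelled-deleted tumour 1, S100a4 was at 0.67 (SE 0.40) and Cdh2 at 0.46 (SE 0.32). The matrix protein gene Tnc went the other way at -0.75 (SE 0.34) and was lower in all 5 libraries labelled deleted. The 10 transcription factors of epithelial-mesenchymal transition had a median of 0.29, with 9 of 10 higher (camera adjusted p = 0.0248), and an adjusted p of 0.444 with an estimated correlation. Twist1 was at 1.04 (SE 0.55), Tcf4 at 0.79 (SE 0.42), Zeb1 at 0.38 (SE 0.23), Zeb2 at 0.18 (SE 0.08), Snai2 at 0.38 (SE 0.28) and Snai1 at 0.19 (SE 0.22). Labelled-deleted tumour 1 held 687 CPM of Tcf4 against at most 200 CPM elsewhere. Without it Twist1 was at 0.37 (SE 0.41), Tcf4 at 0.09 (SE 0.11), Zeb1 at 0.09 (SE 0.11) and Snai2 at 0.20 (SE 0.26). Snai1 ran from 0.07 without wild-type tumour 1 and 0.08 without wild-type tumour 5 to 0.31 without wild-type tumour 4, and Zeb2 was at 0.12 without wild-type tumour 2. The preset call of this list ended without labelled-deleted tumour 1, where its median was 0.16 with an adjusted p of 0.0750. It also ended without labelled-deleted tumour 3 (adjusted p = 0.0589) and without wild-type tumour 2 (adjusted p = 0.0793).

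The lists of BMP signalling genes were not called. BMP target genes had a median log2 fold change of 0.10 over 10 genes (camera adjusted p = 0.395). Among them the inhibitors of differentiation Id1 and Id3, direct targets of BMP signalling, were at 0.17 (SE 0.12) and 0.68 (SE 0.44), and Id4 was at 0.79 (SE 0.31). Smad7, an inhibitory SMAD, was at 0.34 (SE 0.14). Id3 reached 282 CPM in labelled-deleted tumour 1, and without that library its log2 fold change was 0.05 (SE 0.23). Id1 was at 0.26 (SE 0.10) without wild-type tumour 1 and at 0.11 (SE 0.12) without wild-type tumour 2. BMP ligands, receptors and SMADs had a median of 0.11 over 16 genes (camera adjusted p = 0.409), which was 0.04 without labelled-deleted tumour 1 (0.0883), 0.04 without tumour 2 (0.887) and 0.06 without tumour 4 (0.640) of that group. Of these, the ligand Bmp2 averaged 7.34 ± 2.14 CPM in wild-type tumours and 29.9 ± 29.7 CPM in those labelled deleted (SD, n = 5). Its log2 fold change was 2.03 (SE 0.59), and its p adjusted over the list alone was 0.0985. Labelled-deleted tumour 1 held 80.4 CPM of Bmp2, and without it Bmp2 was at 1.24 (SE 0.38) and Smad7 at 0.22 (SE 0.10). BMP antagonists had a median of -0.14 and a mean of 0.08 (camera adjusted p = 0.514), with the abundant Fstl1 at -0.25 (SE 0.12). WNT target genes had a median of 0.15 (camera adjusted p = 0.574) and TGF-beta response genes one of -0.15 (camera adjusted p = 0.0704). The TGF-beta list was called lower without wild-type tumour 2 (adjusted p = 0.0474), 3 (0.0453) or 5 (0.0111), and without labelled-deleted tumour 5 (0.0345). It was also called with no low-count filter (0.0294) and with the Ddx3y covariate (0.0460).

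In the oestrogen receptor and xenobiotic response list, 2 members passed adjusted over the list alone, Greb1 and Tiparp, both higher in the libraries labelled deleted. Their mice had received tamoxifen, a ligand of the oestrogen receptor. Greb1, an oestrogen-induced gene on chromosome 12 (16670615 to 16800886, minus strand, GRCm38), averaged 3.65 ± 2.70 CPM in wild-type tumours and 21.6 ± 10.9 CPM in those labelled deleted (SD, n = 5). Every library labelled deleted, the lowest at 9.07 CPM, lay above every wild-type library, the highest at 8.38 CPM. Its log2 fold change was 2.57 (SE 0.51), with an adjusted p of 0.759 over all genes and 0.00426 adjusted over the list alone. Exons of Greb1 and of Tiparp overlap those of other genes on the opposite strand, and whether the counting used strand is not given in the sources used here. Tiparp, a target of the aryl hydrocarbon receptor and of oestrogen receptors, was at 0.73 (SE 0.20) and passed adjusted over the list alone (adjusted p = 0.0170). It was higher in all 5 libraries labelled deleted, but the lowest of these held 29.9 CPM against 29.7 CPM in the highest wild-type library. Without labelled-deleted tumour 1 Tiparp was at 0.58 (SE 0.17). The progesterone receptor Pgr was at 2.63 (SE 0.94), with an adjusted p of 0.0548 adjusted over the list alone. The wild-type tumours held 0.86, 5.47, 4.79, 0.73 and 3.33 CPM of Pgr, and those labelled deleted 0.80, 7.31, 45.8, 30.8 and 8.81 CPM. Pdzk1, an oestrogen-induced gene chosen after its values were seen, was at 1.28 (SE 0.81). Its level was 13.1 CPM in labelled-deleted tumour 2, the library with intestinal transcripts, and at most 2.31 CPM elsewhere. Abcb1a, a drug efflux pump, was at 0.79 (SE 0.46), and at 0.08 (SE 0.23) without labelled-deleted tumour 2. Over 9 tested genes of the oestrogen receptor and xenobiotic response list the median was 0.79 with 8 higher (camera adjusted p = 0.000695), and the adjusted p with an estimated correlation was 0.444. Without labelled-deleted tumour 2 the median was 0.08 and the preset call ended (adjusted p = 0.1002). That library, which held the intestinal transcripts, had 125 CPM of Abcb1a against at most 42.0 CPM elsewhere.

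The lists of proliferation, interferon and MAPK feedback genes had positive medians in the libraries labelled deleted, and the medians were smaller without labelled-deleted tumour 1. All 20 proliferation genes had a positive log2 fold change, with a median of 0.42 (camera adjusted p = 0.0013), among them Foxm1 at 0.86 (SE 0.43) and Rrm2 at 0.69 (SE 0.38). Their adjusted p with an estimated correlation was 0.689. Without labelled-deleted tumour 1 Foxm1 was at 0.24 (SE 0.23), Rrm2 at 0.29 (SE 0.30) and the median at 0.01 (camera adjusted p = 0.729), and without labelled-deleted tumours 1 and 2 it was -0.32 (camera adjusted p = 1.44e-06). Interferon response genes had a median of 1.43, with 16 of 18 higher (camera adjusted p = 0.000694), and an adjusted p of 0.609 with an estimated correlation. Ifit1 was at 3.02 (SE 1.07), Usp18 at 3.07 (SE 1.11), Ifit3 at 3.17 (SE 1.17) and the chemokine gene Cxcl10 at 1.91 (SE 0.75). Ifit1 stood at 265 CPM in labelled-deleted tumour 1 and at 6.14 to 21.5 CPM in the other 4 libraries labelled deleted. Without tumour 1 Ifit1 was at 0.74 (SE 0.47), Usp18 at 0.63 (SE 0.46), Ifit3 at 0.56 (SE 0.51) and Cxcl10 at 0.59 (SE 0.39). The list's median was then 0.08 (camera adjusted p = 0.187), and without wild-type tumour 2 the preset call also ended (adjusted p = 0.0874). Ifit3 has close relatives in the genome, so its count could include reads of them. MAPK feedback genes had a median of 0.45 (camera adjusted p = 0.000836, and adjusted p = 0.568 with an estimated correlation), with Spry2 at 0.68 (SE 0.28) and Etv1 at 1.18 (SE 0.53). Without labelled-deleted tumour 1 their median was 0.19 (camera adjusted p = 0.0699), Spry2 was at 0.32 (SE 0.14) and Etv1 at 0.30 (SE 0.21).

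Hypoxia and glycolysis genes had a median of 0.27, with 13 of 16 higher (camera adjusted p = 0.00118, and adjusted p = 0.568 with an estimated correlation). The stress-responsive gene Ndrg1 was higher in all 5 libraries labelled deleted at 0.40 (SE 0.15), and the vasoactive peptide gene Adm was at 1.29 (SE 0.49). Labelled-deleted tumour 1 held 37.0 CPM of Adm against at most 14.7 CPM elsewhere, and without it Adm was at 0.64 (SE 0.31). Without labelled-deleted tumour 2 Ndrg1 was at 0.22 (SE 0.07). Targets of p53 had a median of -0.26, with 10 of 12 lower (camera adjusted p = 0.00254), and an adjusted p of 0.568 with an estimated correlation. Sesn2 was at -0.39 (SE 0.16) and Ccng1 at -0.30 (SE 0.14). Without labelled-deleted tumours 1 and 2 the preset calls of both lists ended, with a median of 0.0065 (adjusted p = 0.890) for hypoxia and glycolysis genes and -0.07 (adjusted p = 0.336) for p53 targets. Immediate early and heat shock genes, which respond to handling of tissue, had a median of 0.51 (camera adjusted p = 0.00376, and adjusted p = 0.599 with an estimated correlation). Hspa1a was at 1.14 (SE 0.38), a value that could include reads of its near-identical neighbour Hspa1b, and Fosb was at 1.75 (SE 0.78). Without labelled-deleted tumour 3 this list's median was 0.04 (camera adjusted p = 0.730) and Fosb was at 0.32 (SE 0.42).

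**Figure D3:**
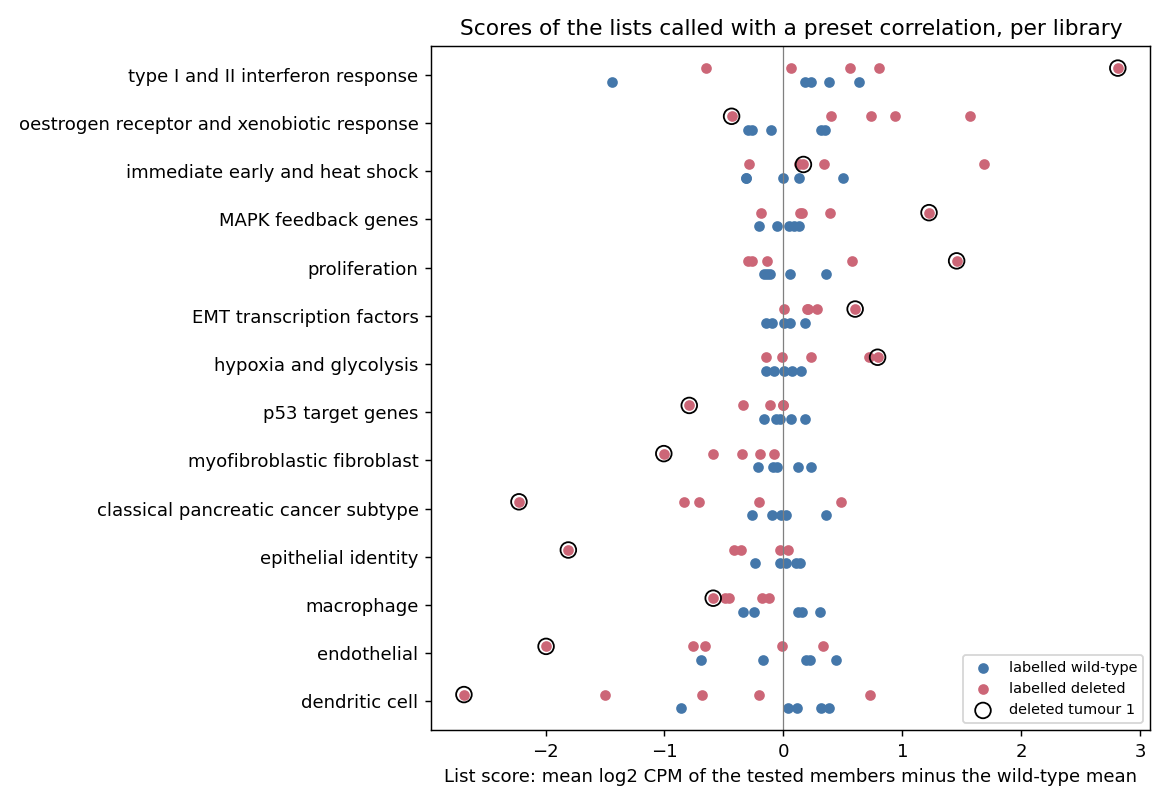
Score of each library (horizontal axis, mean log2 CPM of the tested members minus the wild-type mean) for the 14 lists called with the preset correlation, ordered by median log2 fold change; blue points are libraries labelled wild-type, red points those labelled deleted, and a black ring marks labelled-deleted tumour 1. That tumour lies at -1.81 for epithelial identity and at 2.81 for interferon response.

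The fibroblast lists had different medians, and the differences between them were not tested. The 11 myofibroblastic genes had a median of -0.31, with 9 lower (camera adjusted p = 0.00118), and an adjusted p of 0.444 with an estimated correlation. Thbs2 was at -0.47 (SE 0.14, adjusted p = 0.0678 adjusted over the list alone), and the collagen gene Col12a1 at -0.69 (SE 0.34). The 13 pan-fibroblast genes had a median of -0.07 and were not called (camera adjusted p = 0.191). They were called lower without labelled-deleted tumour 3 (median -0.30, adjusted p = 0.0471) or 4 (median -0.21, adjusted p = 0.0429). Within them the receptor Pdgfra was at 0.75 (SE 0.20, adjusted p = 0.0523 adjusted over the list alone). The fibroblast activation protein gene Fap was at -0.89 (SE 0.28), and the microfibril gene Mfap5 at -0.73 (SE 0.25). Inflammatory fibroblast genes had a median of 0.01 (camera adjusted p = 0.696). All 12 endothelial genes had a negative log2 fold change, with a median of -0.44 (camera adjusted p = 5.37e-05), and an adjusted p of 0.568 with an estimated correlation. Emcn was at -0.96 (SE 0.45) and VE-cadherin (Cdh5) at -0.42 (SE 0.26). The endothelial median was -0.24 without labelled-deleted tumour 1, and it was -0.74 without labelled-deleted tumour 3. Without labelled-deleted tumours 1 and 2 it was -0.10 and the preset call ended (adjusted p = 0.328). The myofibroblastic median was -0.47 without labelled-deleted tumour 1 and -0.20 without wild-type tumour 1.

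Macrophage genes had mostly lower values in the libraries labelled deleted, among them those of the complement component C1q. C1qa, C1qb and C1qc, adjacent genes on chromosome 4 that mark tissue macrophages, had log2 fold changes of -0.61 (SE 0.20), -0.65 (SE 0.20) and -0.57 (SE 0.17). Each passed adjusted over the list alone (adjusted p = 0.0476) and failed over all genes (adjusted p = 0.759). C1qa averaged 588 ± 139 CPM in wild-type tumours and 386 ± 84.4 CPM in those labelled deleted (SD, n = 5). The mannose receptor Mrc1 was at -0.40 (SE 0.20), and at -0.25 (SE 0.17) without wild-type tumour 4. Of 13 macrophage genes, 11 were lower, with a median of -0.43 (camera adjusted p = 6.08e-05), and the adjusted p was 0.462 with an estimated correlation. The C1qa log2 fold change kept its sign in all 10 fits that left out 1 library, from -0.71 to -0.50. Dendritic cell genes had a median of -0.53 (camera adjusted p = 0.0043, and adjusted p = 0.599 with an estimated correlation), with Cd209a at -1.38 (SE 0.73) and Batf3 at -0.98 (SE 0.54). Without labelled-deleted tumour 1 their median was -0.24 and the preset call ended (adjusted p = 0.0885). Without labelled-deleted tumour 3 their median was -0.94.

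Lymphocyte content varied widely between tumours of both groups. The B and plasma cell score ranged from -1.89 to 2.85 in wild-type tumours and from -1.71 to 4.16 in those labelled deleted, on a log2 scale. The list had a median log2 fold change of 1.07 and was not called (camera adjusted p = 0.0704). Jchain, a chain of secreted immunoglobulins, was at 2.03 (SE 0.97). T and NK cell genes had a median of 0.83 (camera adjusted p = 0.266), with perforin (Prf1) at 2.90 (SE 1.20). Labelled-deleted tumour 1 held 19.4 CPM of Prf1 against at most 1.89 CPM elsewhere, and without it Prf1 was at 0.68 (SE 0.74). The calls of both lists changed with single libraries. Both medians turned negative without labelled-deleted tumour 3, at -1.12 and -0.31. The B and plasma cell list was called higher without labelled-deleted tumour 1 (median 1.37, adjusted p = 0.0014), 2 (1.36, 0.0176) or 4 (1.28, 0.0250) and without wild-type tumour 3 (2.50, 0.000175). The T and NK cell list was called higher without labelled-deleted tumour 1 (median 1.06, adjusted p = 0.0148), 2 (1.10, 0.0169) or 4 (1.07, 0.00981). It was also called without wild-type tumour 1 (0.82, 0.0363), 3 (1.19, 0.0453) or 5 (1.26, 0.0128). With an estimated correlation and labelled-deleted tumour 1 left out, both had an adjusted p of 0.602. Upper-quartile scaling called the B and plasma cell list (adjusted p = 0.0419), as did the replicate block (0.00608) and the Ddx3y covariate (0.0243), and the T and NK cell list was called with no low-count filter (0.0186). Acinar scores, which reflect normal exocrine pancreas, ranged from -4.46 to 4.65 in wild-type tumours and from -3.05 to 4.46 in those labelled deleted, and the acinar list was not called (median 0.09, mean -0.03, camera adjusted p = 0.766). It was called higher without wild-type tumour 5 (median 2.26, adjusted p = 0.000432) and without labelled-deleted tumours 1 and 2 (median 0.82, adjusted p = 0.00108). The Y-linked gene Ddx3y was above 1 CPM in 1 of 5 libraries of each group.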

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

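The tests of fibroblast content and of leftover reads for Grem1, and that of splits for the number of changed genes, were chosen after the results were seen. In groups of 5, a library was singled out when its gap to the nearest other library exceeded 0.71 of the group's range. Of 194 groups of values examined, 13 met this, where chance gives about 10. Labelled-deleted tumour 1 accounted for 7. It was lowest among the libraries labelled deleted for Muc5ac (gap 0.807 of the range), Mfap5 (0.919) and the scores of epithelial identity (0.754), the basal-like subtype (0.775) and WNT target genes (0.836). It was highest for Tcf4 (0.780) and Spry2 (0.732). Labelled-deleted tumour 2 was highest for Ndrg1 (0.835). Wild-type tumour 1 was highest for Thbs2 (0.797), and wild-type tumour 3 was highest for Rrm2 (0.758). Wild-type tumour 2 was lowest for the interferon response (0.783), inflammatory fibroblast (0.819) and dendritic cell (0.726) scores.

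Grem1 was not lower in the libraries labelled deleted, at a log2 fold change of 1.08 (SE 0.79). The pan-fibroblast score gave no sign of a higher fibroblast content: it differed by -0.19, with an upper bound of 0.276 (2 SE). That bound lies under the rise of 0.50 that would bring a halved Grem1 to the lower end of its interval. The halving is assumed, and members of the score went both ways, with Pdgfra at 0.75 (SE 0.20) and Fap at -0.89 (SE 0.28). The score therefore cannot exclude more fibroblasts of some kind. A single wrongly labelled library stays open, since over the fits without 1 library the lower bound reached -1.16, in the fit without labelled-deleted tumour 2, the library with intestinal transcripts. Without labelled-deleted tumours 1 and 2 together Grem1 was at -0.40 (SE 0.71), but they held the most Grem1 of their group, so that fall says nothing about labels. Reads from a part of the gene left in the deleted allele stay open too. The coding sequence is 552 of 4148 exonic bases, a deletion of it alone would leave 86.7% of the exonic length (-0.21 on a log2 scale), and the lower bound of Grem1 was -0.50. Incomplete deletion, or deletion in cells other than those that express Grem1, was not tested.

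Camera with its preset correlation called 14 lists. Of 100 splits of the 10 tumours drawn from 126, 42 gave at least as many lists, up to 20, so chance cannot be excluded as the source of that number. The real split is among the 100, here and in the counts of splits below. Labelled-deleted tumour 1 may account for part of it: 9 of the 14 lists were still called in the same direction without it, which leaves open how far that library alone set the count. The biological explanation, a group effect of the deletion or of tamoxifen, cannot be told apart from these with this test.

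For the number of changed genes in edgeR's test, other splits decide nothing: a real count of 0 is met by all 100 splits, whatever the data, and the highest other split gave 1. DESeq2 called 7 genes, and its splits were not run. At an unadjusted p under 0.05 the real split gave 983 genes, and 18 of the 100 splits gave as many, up to 3251. That split, of wild-type tumours 1, 4 and 5 with labelled-deleted tumours 3 and 5 against the rest, calls several times the real count, which points to a structure of the samples other than their labels. Adjusted over each list alone, 7 members of the lists passed, and 32 of 100 splits gave as many, up to 57.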

How the results depend on the processing

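The B-cell covariate, the estimated correlation without labelled-deleted tumour 1 and the fit without labelled-deleted tumours 1 and 2 were chosen after the data were seen. Genes and lists were followed across alternatives, though not every list (TGF-beta response and acinar, for example, are not among them). Of their values, 2101 kept their direction and their side of the threshold, or stayed within 1.5 times. A further 65 lost a call, 22 gained one, 26 reversed and 4 counts moved. Outside DESeq2 no gene passed in any fit, so for genes a kept side of the threshold was largely fixed in advance. The count of 2101 therefore says little about robustness. The number of changed genes was 0 under every alternative run except DESeq2, which gave 7 and was fitted to 31198 genes. In simulated data with nothing changed DESeq2 gave 18, and the cause was not tested. The simulation held only genes kept by edgeR's filter, drawn independently and once, so the 18 cannot be set directly against the 7. Fits without 1 library gave 0 genes each and 12 to 18 called lists. The Grem1 log2 fold change ran from 0.25 to 1.60 without 1 library. It was positive in every other fit except that without labelled-deleted tumours 1 and 2, where it reversed to -0.40 and Spink4 to -0.40, Foxm1 to -0.0064, Rrm2 to -0.15, the proliferation median to -0.32 and the pan-fibroblast median to 0.020. The 14 called lists became 0 with an estimated correlation, 0 with fry, and 0 with an estimated correlation without labelled-deleted tumour 1, and the estimated correlations of the called lists ran up to 0.88.

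Whether the replicate numbers pair the tumours stays open. Correlations of same-numbered deviations ran from -0.016 to 0.39, and 4 of 10 libraries matched their own number best. With the number as a block there were 0 changed genes and 15 called lists, Grem1 was at 0.87, and Spink4 reversed to -0.019. With the tumour ID number as a block on 8 libraries, without labelled-deleted tumours 1 and 4 whose numbers are not shared, Twist1 was at -0.10, the proliferation median at -0.037 and the BMP antagonists median at 0.12. In that fit the EMT factor, classical, proliferation, hypoxia, MAPK feedback, endothelial and dendritic lists were not called. Block and left-out libraries were not separated. The causes were not tested.

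Other reversals came from leaving out 1 library. The ranges were -0.084 to 0.057 for the mesenchymal median, -0.0041 to 0.19 for BMP target genes, -0.20 to 0.087 for BMP antagonists, -0.68 to 3.88 for Spink4, -1.12 to 2.50 for B and plasma cells, and -0.31 to 1.26 for T and NK cells. With the B-cell covariate the medians were 0.0092 for mesenchymal genes, -0.22 for B and plasma cells and -0.19 for T and NK cells. That covariate is the mean of the B and plasma cell list itself. The list was thus adjusted for itself, and its own median in that fit says nothing about the groups. With an estimated correlation without labelled-deleted tumour 1 they were -0.0041 for BMP target genes and 0.087 for BMP antagonists. The cause of the other reversals was not tested. With 10159891 counts in the smallest library, depth limits only genes of a few CPM.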

Other observations

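The genes of this paragraph and the fits without labelled-deleted tumours 1 and 2 together or with a B-cell covariate were chosen after the data were seen. Some genes had a higher value in 1 tumour than in the other 9. Labelled-deleted tumour 2, which held the intestinal transcripts, also had 56.3 CPM of Spink4, 234 CPM of the brush border myosin Myo1a and 164 CPM of the sodium-glucose transporter Slc5a1, where the other 9 libraries held at most 2.2, 12.6 and 8.77 CPM. Its Vil1, another brush border gene, was at 264 CPM against 27.4 to 121 CPM elsewhere. The intestinal transcription factor Cdx2 was at 35.1 CPM against at most 1.07 CPM. Labelled-deleted tumour 1 held 100.2 CPM of the transcription factor Pax6, against at most 4.06 CPM elsewhere, and 451 CPM of Irf7, against at most 56.7 CPM. Labelled-deleted tumour 3 held 49.9 CPM of the hyaluronan synthase gene Has1, against at most 7.47 CPM.

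The remaining cell type lists were not called with all 10 libraries and no covariate: the median log2 fold change was 0.36 for mesothelial genes (camera adjusted p = 0.598), -0.14 for neutrophils (0.473), -0.24 for Schwann and nerve genes (0.266), 0.44 for adipocytes (0.654) and -0.18 for erythroid genes (0.145). It was -0.05 for hepatocytes, with a mean of -0.35 (0.346), and -0.38 for islets, with a mean of 0.05 (0.562). Some were called by camera with its preset correlation in other fits. Mesothelial genes were called higher without labelled-deleted tumour 1 (median 0.54, adjusted p = 0.00119) and without labelled-deleted tumours 1 and 2 (0.65, 1.78e-05), where islet (0.32, 0.0271) and adipocyte (0.84, 0.0331) genes were also called higher. With an estimated correlation and labelled-deleted tumour 1 left out, mesothelial genes had an adjusted p of 0.421; the other fits here with libraries left out, a covariate or a block were not run with an estimated correlation. Islet genes were called lower without wild-type tumour 1 (-0.25, 0.0142), and neutrophil genes without wild-type tumour 4 (-0.44, 0.0451). Erythroid genes were called lower without wild-type tumour 5 (-0.23, 0.0443), without labelled-deleted tumour 3 (-0.79, 0.000861) and with the B-cell covariate (-0.82, 0.00176). With the tumour ID number as a block, without labelled-deleted tumours 1 and 4, mesothelial (0.42, 0.00367), islet (0.59, 0.00198), adipocyte (1.07, 0.0196), acinar (1.90, 9.77e-17), T and NK cell (1.11, 0.000268) and B and plasma cell (1.09, 4.22e-06) genes were called higher. Among WNT target genes Lgr5 was at -0.84 (SE 0.33) and Notum at 0.97 (SE 0.38).

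A candidate explanation for the higher Greb1 and Tiparp in the libraries labelled deleted is an action of tamoxifen on oestrogen receptors in the tumour. It is a hypothesis: all mice of that group, and no others, received tamoxifen, so it cannot be told apart here from an effect of the deletion. Of 100 splits of the tumours, 3 gave at least the 2 members of that list that passed adjusted over the list alone. The real split is 1 of these 3, and the highest other split gave 2. Taken alone, that list would seldom reach 2 by chance, but it was singled out after 33 were seen, so chance is not excluded. For Greb1, the data gave no sign of more cells that express Esr1, the oestrogen receptor gene, as the main source. Esr1 itself was at 0.03 (SE 0.42), though its RNA level in a tumour does not count such cells. With Esr1 as a covariate Greb1 was at 2.62 (SE 0.48) against 2.57 without. A covariate with so small a difference between the groups could hardly move Greb1, so that fit decides nothing. It was run for Greb1 alone, not for Tiparp or Pgr. Labelled-deleted tumours 3 and 4 held the most Esr1 (29.7 and 19.4 CPM) and the most Pgr (45.8 and 30.8 CPM), and labelled-deleted tumour 1 was low in both (6.32 and 0.80 CPM). Other libraries went against such a link. Wild-type tumour 3 held 19.3 CPM of Esr1 but 4.79 CPM of Pgr. Labelled-deleted tumour 2 held the least Esr1 (5.96 CPM) but 7.31 CPM of Pgr, above every wild-type library. For Pgr, such cells stay open as a source.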
